A study of Mus musculus with 12 samples.

How the data were processed

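The table holds digital counts of messenger RNAs from the oviducts of 12 CD1 mice, an outbred stock, measured on the nCounter GX Mouse Inflammation panel. On this platform a pair of probes binds each mRNA and single fluorescent barcodes are counted, without amplification. Per the labels' protocols, mice aged 6 to 8 weeks received lipopolysaccharide (LPS, a cell wall component of Escherichia coli) intraperitoneally on the day of estrus, in 100 µL of phosphate-buffered saline. Control mice received 0 µg, low-dose mice 2 µg and high-dose mice 10 µg, with 4 mice per group. Oviducts were collected 24 h later, and total RNA had an integrity number above 9.7 and a 28S/18S ratio above 2.0 in all samples, per the labels' protocols.

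The authors deposited 1 table of raw counts, 1 column per mouse and lane, all 12 lanes from 1 run. It was handled under the rules for estimated counts (expected counts) because the deposited columns also hold a decimal line for binding density. Every probe value is a whole number, so rounding changed nothing. Of the 2388 values, 95 were at 1, the smallest value. The table holds 185 endogenous probes, 8 negative control probes and 6 positive control probes for spiked RNAs. The 185 endogenous probes are 179 inflammation genes and 6 reference genes (Cltc, Gapdh, Gusb, Hprt1, Pgk1 and Tubb5). Steps in the instrument software before these counts are not given in the sources used here. Gene symbols are those of the table. A RefSeq table of the GRCm38.p6 assembly, used for names only, matched 179 of the 185 probe accessions. For 8 of them the current symbol differs, among them Il8rb (now Cxcr2), Il8ra (now Cxcr1), C1r (now C1ra) and C1s (now C1s1). No genome was used, so no coordinates are given.

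Groups were taken from the sample titles. The lanes were scaled by the geometric mean of the 6 reference genes, and scaled counts are counts divided by that scale, which has a geometric mean of 1 over the lanes. A gene was tested when its raw count lay above the mean plus 2 SD of the lane's negative control probes in at least 4 of the 12 lanes. This kept 165 genes and left out 14. The counts were tested with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood fits of all 12 lanes with the reference scale as offset. Tested were low dose minus control, high dose minus control, high minus low dose, and both doses together against control. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the F statistic. Where no control lane lay above the negative controls, a bound is given as "at least" that fold, against the negative control limits of the control lanes. Gene lists were tested for a shift in one direction with fry (limma 3.58.1), adjusted over the 17 lists with at least 3 tested members of the 18 lists. Fry does not compare a list with other genes. The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined.

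The lists were interferon-stimulated genes, complement components, chemokine ligands, chemokine receptors, innate cytokines, lymphocyte cytokines, pattern recognition receptors and adaptors, NF-kB and TNF signalling, MAP kinases and AP-1, the prostanoid pathway, the TGF-beta family, macrophage and monocyte markers, alternative activation markers, neutrophil markers, T and NK cell markers, antigen presentation, muscle and vessel genes, and small G proteins and actin regulators. Named are, of the genes past the threshold, the 14 highest and 14 lowest log2 fold changes at the high dose and the 8 highest and 8 lowest in the other comparisons. Where fewer than 5 genes passed, the 5 of smallest p are named as well. For each described list up to 2 highest and 2 lowest members past the threshold at the high dose are named. Tlr4, Il1b, Tnf, Il6, Nos2, Cxcl1, Ccl2, Cxcl10 and the reference genes are named whatever their values. Genes named beyond this rule were chosen after their values were seen, which is said where most of them appear. Named beyond it without such a statement are C3, Ccr2, Nox1, Pla2g4a and list members that did not pass. Some genes that the rule names are not reported here.

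The procedure was tested on simulated data for high dose against control, with counts of the 165 genes drawn from the control means and lane scales and 40 genes changed in each of 20 runs. It recovered 86.5% of 4-fold and 56% of 2-fold changes, and 83.5% of 2-fold changes in genes with a control mean of at least 100. Of all calls 4.20% were false. As many of the changed genes fell as rose, and the reference genes were drawn without a change, so this share leaves out errors of the scale. No lanes were duplicates: the lowest chi-square per degree of freedom over the 18 pairs of lanes within groups was 16.1. Alternatives were other scalings (TMM, DESeq2 size factors, total count, positive controls, and 4 of the reference genes, without Gapdh and Pgk1), DESeq2 1.42.0, limma-voom, the series' own test, which is a one-way analysis of variance followed by least significant differences, other filters, background subtraction, fits of the groups compared alone, the replicate number as a block, and each mouse left out. A fit without the 2 lanes in which under 75% of the fields of view were counted was chosen after seeing the data.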

Results

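Counts of 185 endogenous mRNAs were obtained from the oviducts of 12 mice, 4 without LPS, 4 given 2 µg and 4 given 10 µg. The comparisons ask how the dose of LPS changed inflammatory mRNAs in the oviduct 24 h later. Endogenous counts per lane ranged from 98258 to 196878, with means of 116830 ± 12566 in controls, 146836 ± 15628 at the low dose and 165671 ± 28250 at the high dose (SD, n = 4 each). C3, the central complement protein, took 8.86% ± 3.32 of the counts in controls, 13.6% ± 4.04 at the low dose and 22.7% ± 1.98 at the high dose (SD, n = 4). The share of fields of view counted was 62.3% to 90.2%, and 2 control lanes (mice 2 and 4) lay below 75%. Each count carries counting error, so genes with few counts are measured least precisely.

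The high dose raised chemokines, complement components and other inflammatory mRNAs in the oviduct. Cxcl9, an interferon-induced chemokine for T cells, rose most, from a scaled count of 4.80 ± 3.20 in controls to 214.8 ± 88.5 (SD, n = 4), a log2 fold change of 5.40 ± 0.94 (SE). Its raw counts in control mice 2 and 4, 1 and 3, lay below the negative control limits of 6.05 and 5.33. The size of this fold change thus rests in part on counts near the background. Ccl5, a chemokine for T cells and monocytes, rose from 32.9 ± 10.8 to 867.7 ± 288.7, and Cfb, complement factor B, from 81.4 ± 36.8 to 2131 ± 561 (SD, n = 4). Tlr4, the receptor for LPS, did not pass, at a log2 fold change of 0.29 ± 0.14 (SE, adjusted p = 0.161), though it passed without control mouse 2. Of 165 genes tested with edgeR's quasi-likelihood test, 37 were higher than in controls and 0 lower, by 1.34-fold to 42.2-fold, and 33 of them by over 2-fold. At an unadjusted p below 0.05 there were 53 genes, all 53 higher. In 34 of the 37 genes every high-dose mouse lay above every control mouse, as in 42 of the 165 tested, where chance gives 1.43% of genes.

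The split of higher and lower genes at the high dose depended on the scaling. Scaling by TMM gave 34 higher and 20 lower, DESeq2 size factors 34 and 25, total count 30 and 62, and DESeq2 itself 35 and 31. The positive control probes gave 38 and 0, and 4 of the reference genes 36 and 0. The median log2 fold change of the 165 genes was 0.24 on the reference scale, 0.20 by positive controls, 0.00 by TMM, -0.02 by DESeq2 size factors and -0.34 by total count. The genes that were lower by TMM included Rhoa, Rac1 and Cdc42, which were chosen after their values were seen. By TMM over all genes, the reference genes all lay below 0 at the high dose, from -0.34 to -0.04. The reference genes are themselves among the genes that set this scale. By edgeR, Cltc (-0.33 ± 0.08, SE, adjusted p = 0.00803) and Hprt1 (-0.34 ± 0.09, adjusted p = 0.0169) passed, while Gapdh, Gusb, Pgk1 and Tubb5 did not. By positive controls 0 of the 6 reference genes passed.

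**Figure D1:**
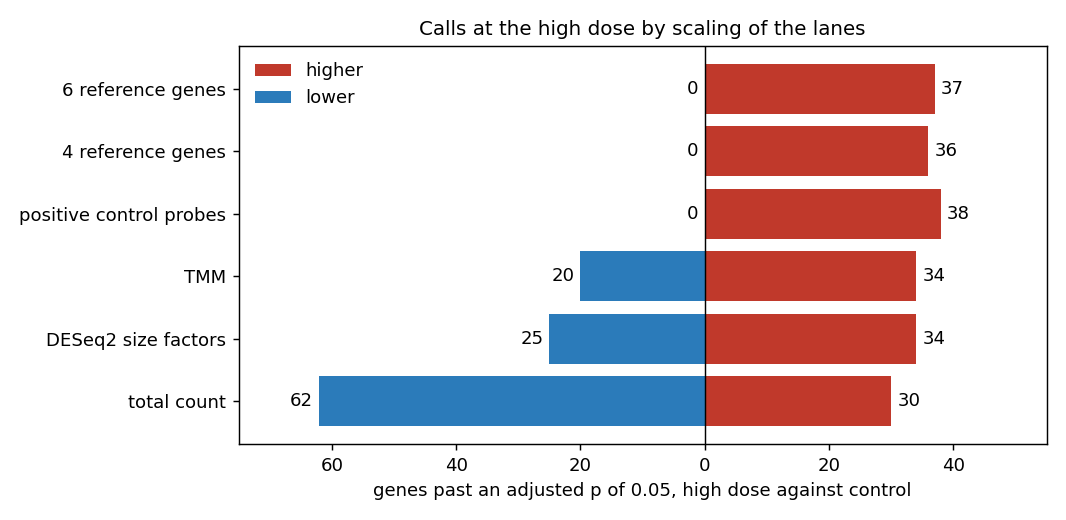
Genes higher (right) and lower (left) at the high dose than in controls at an adjusted p below 0.05, for 6 scalings of the lanes, as numbers of the 165 genes tested. The 6 reference genes gave 37 higher and 0 lower, and the total count 30 higher and 62 lower.

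Chemokine ligands, which attract leukocytes, formed the largest group of rises: 12 of 18 rose at the high dose (13 adjusted over the list alone), with a list shift by fry of adjusted p = 0.000418. The monocyte chemokines Ccl7 and Ccl2 rose by 4.05 ± 0.56 and 3.75 ± 0.47, Ccl8 by 3.12 ± 0.46 and Cxcl10 by 3.92 ± 0.45 (log2, SE). The neutrophil chemokines Cxcl1 and Cxcl5 rose by 2.80 ± 0.44 and 2.75 ± 0.69. Raw counts of Ccl7 in control mice 2 and 3 (4 and 5) did not exceed the negative controls. Nor did those of Cxcl5 in control mice 1 and 3 (2 and 4). Ccl3 rose by 1.71 ± 0.37 and Ccl19, a ligand of Ccr7, by 1.40 ± 0.31. Cxcl2 passed too, but in 0 of 4 control lanes and 3 of 4 high-dose lanes did it exceed the negative controls. The Cxcl2 call was lost with DESeq2, with background subtraction and without control mouse 3, control mouse 4 or high-dose mouse 3.

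Of the complement components, 9 of 16 rose at the high dose (9 adjusted over the list alone; fry adjusted p = 0.00347). Beside Cfb (4.71 ± 0.66) these were led by the classical pathway proteases C1s, from 2731 ± 1138 to 12075 ± 2039 (SD, n = 4), and C1r, by 2.07 ± 0.27 (log2, SE). C3ar1, the C3a receptor, rose by 1.23 ± 0.29 and C2 by 1.18 ± 0.29 (log2, SE). After adjustment the series' own test did not call C1qa, C1qb, C2 or C3ar1, nor, outside complement, Ccr7, Cxcl2, Cxcl5, Il1b, Itgb2, Ltb, Ly96 or Tgfb1. The 7 members that did not pass were C6, C7, C8b, Cfd, Hc, Masp1 and Masp2.

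Only 3 members of the interferon-stimulated list were on the panel, and all 3 rose (3 over the list alone; fry adjusted p = 0.000418), Cxcl9 and Cxcl10 among them. Of the innate cytokines 5 of 16 rose (7 over the list alone; fry adjusted p = 0.0105, a list call lost by total count, 0.376). Il1b rose from 22.6 ± 10.3 to 53.9 ± 11.7 (SD, n = 4), Tnfsf14 by 1.25 ± 0.26, Ltb by 1.02 ± 0.27, Csf1, a macrophage growth factor, by 0.91 ± 0.16 and Il15 by 0.81 ± 0.16 (log2, SE). By total count 4 of these 5, all but Csf1, lost their calls. The Il1b call was also lost without high-dose mouse 3, and that of Ltb without control mouse 1 or high-dose mouse 3. Tnf did not pass (2.06 ± 0.72, log2, SE; adjusted p = 0.0611, passing without control mouse 2, high-dose mouse 1 or any one of low-dose mice 2, 3 and 4), nor did Nos2 (0.93 ± 0.32; adjusted p = 0.0595) or Il6 (0.75 ± 0.97; adjusted p = 0.655).

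Among receptors, 2 of 8 chemokine receptors rose (4 over the list alone; fry adjusted p = 0.0015, a list call lost with the filter on all 12 lanes, 0.115). Il8rb, a neutrophil chemokine receptor, was at 4.45 ± 1.28 in controls, where 0 of 4 lanes exceeded the negative controls, and at 46.78 ± 11.99 at the high dose (SD, n = 4), at least 7.57-fold higher. Ccr7, which guides dendritic cells and T cells, was at least 1.92-fold higher, a call lost without control mouse 1, 2 or 4 or high-dose mouse 2 or 3. Of the pattern recognition receptors and adaptors 2 of 11 rose (2 over the list alone; fry adjusted p = 0.00951, a call lost by DESeq2 size factors, and a shift downwards by total count, adjusted p = 0.00211). These were Tlr2 (1.48 ± 0.29, log2, SE) and Ly96, the partner of Tlr4 (0.42 ± 0.12). Ly96 lost its call by TMM, by both size factors and test of DESeq2, by positive controls and without any one of control mice 1, 3 and 4 and high-dose mice 2, 3 and 4, and by total count it lay at -0.16.

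Some markers of leukocytes rose at the high dose, where 37 of all 165 genes tested rose. Of the macrophage and monocyte markers 3 of 4 rose (3 over the list alone; fry adjusted p = 0.0105), and these 3, C1qa, C1qb (1.39 ± 0.31, log2, SE) and C3ar1, are also complement genes, while Ccr2 stood at 0.17 ± 0.42. Without control mice 2 and 4 this list shift had an adjusted p of 0.057, and by total count 0.0503. Without these 2 mice C1qa, Itgb2, Ccr7, Cxcl2, Ltb, Ly96 and Tgfb1 lost their calls as well. Of the neutrophil markers 2 of 3 rose (3 over the list alone; fry adjusted p = 0.000159), Il8rb and Itgb2, an integrin of many leukocytes (1.23 ± 0.31). Of the T and NK cell markers 2 of 7 rose (2 over the list alone; fry adjusted p = 0.00324), Il18rap (1.58 ± 0.28) and Il23r (1.47 ± 0.30). The T and NK cell markers Ccr4, Cd4, Cd40lg, Fasl and Lta did not pass. For antigen presentation 2 of 4 rose, Ccr7 and Cd40 (1.45 ± 0.27), with a list shift of adjusted p = 0.0711. This list passed by fry with only the 2 groups fitted (adjusted p = 0.00883) and without low-dose mouse 2 or 3.

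On the reference scale 4 lists of signalling and structural genes held no gene past the threshold, and their list tests did not pass. Of the MAP kinase and AP-1 genes 0 of 25 passed (fry adjusted p = 0.673), of NF-kB and TNF signalling 0 of 6 (0.134), of muscle and vessel genes 0 of 6 (0.227), and of small G proteins and actin regulators 0 of 10 (0.738). Without control mouse 2 the lists of NF-kB and TNF signalling and of muscle and vessel genes shifted upwards by fry. By TMM the MAP kinase list shifted downwards (adjusted p = 0.00205), as did the small G protein list (0.00562). By total count all 4 of these lists, the TGF-beta family and the alternative activation markers shifted downwards, each with an adjusted p of at most 0.0322. Of the TGF-beta family 1 of 4 passed, Tgfb1 (0.48 ± 0.14, log2, SE), with a list shift of adjusted p = 0.0591. The list passed by fry with only the 2 groups fitted (adjusted p = 0.0343) and without control mouse 3, low-dose mouse 1 or 3 or high-dose mouse 1. The Tgfb1 call was lost by TMM, by both size factors and test of DESeq2 and by positive controls. It was also lost without any one of control mice 1, 2 and 4 and high-dose mice 2, 3 and 4. By total count Tgfb1 lay at -0.11. Of 3 alternative activation markers 0 passed (adjusted p = 0.781). Of 4 lymphocyte cytokines 0 passed, though the list shifted upwards (adjusted p = 0.0406). This list call was lost in 7 of the 12 fits with 1 mouse left out and in 8 of the 10 other alternatives that tested the list, among them TMM (0.334). Pla2g4a, the prostanoid pathway gene tested, stood at -0.18 and did not pass. It was called lower by DESeq2 size factors, by total count and with DESeq2 itself.

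**Figure D2:**
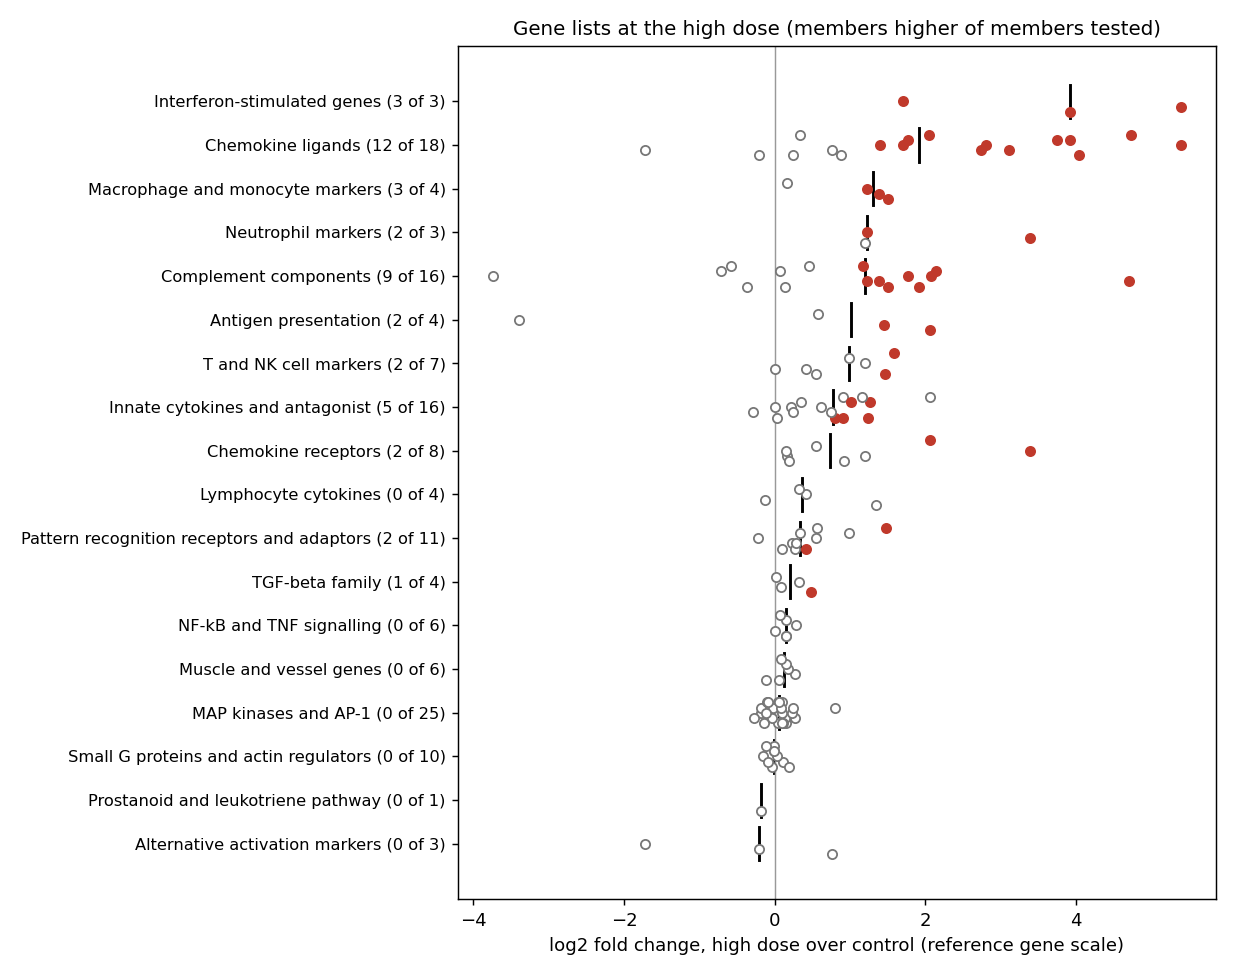
Log2 fold changes of single genes at the high dose over control on the reference gene scale, by gene list. Filled points passed an adjusted p of 0.05, open points did not, and the black bar is the median of the list. Of the chemokine ligands 12 of 18 passed, and of the MAP kinase and AP-1 genes 0 of 25.

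At the low dose 4 genes were higher than in controls and 0 lower by edgeR. Cfb rose to 680.6 ± 608.4 (SD, n = 4), with a log2 fold change of 3.07 ± 0.61 (SE), and Ccl8 rose by 2.22 ± 0.45. Ccl5 rose to 607.3 ± 652.0, 4.21 ± 0.89 on the log2 scale. Il8rb was at 21.9 ± 7.87 (SD, n = 4), at least 3.50-fold above controls. Of the genes that did not pass, Cxcl10 had the smallest p (1.74 ± 0.42, log2, SE; adjusted p = 0.0537). All 4 genes were also among the 37 of the high dose. Il1b (0.48 ± 0.35), Ccl2 (1.25 ± 0.43), Cxcl1 (0.61 ± 0.46), Nos2 (0.34 ± 0.33), Tnf (0.67 ± 0.76), Il6 (0.19 ± 0.99) and Tlr4 (0.08 ± 0.14) did not pass. Of the gene lists, those of neutrophil markers (1 of 3 members higher, 3 over the list alone; fry adjusted p = 0.00121) and chemokine receptors (1 of 8 higher, 1 over the list alone; 0.0417) shifted upwards. The chemokine receptor shift was lost in 10 of the 12 fits with 1 mouse left out, with only the 2 groups fitted, with the filter on all 12 lanes and without control mice 2 and 4. The neutrophil marker shift was kept in every alternative in which the list was tested, which the filter on all 12 lanes did not allow. It rests in part on counts near the background. Il8ra had raw counts of 1 to 3 in controls and 4 to 8 at the low dose. In controls neither Il8ra nor Il8rb exceeded the negative controls.

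Unadjusted, 21 genes were higher and 2 lower at the low dose. The count of 4 rested on single mice. It was 14 without low-dose mouse 3, 2 without control mouse 1 or low-dose mouse 2, 1 without control mouse 2, 3 or 4 or low-dose mouse 1, and 0 without control mice 2 and 4 together. Il8rb remained in each of the fits with 1 mouse left out. The Ccl8 call was lost by TMM and DESeq2 size factors, those of Ccl5 and Cfb with limma-voom, and all 3 with only the 2 groups fitted.

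**Figure D3:**
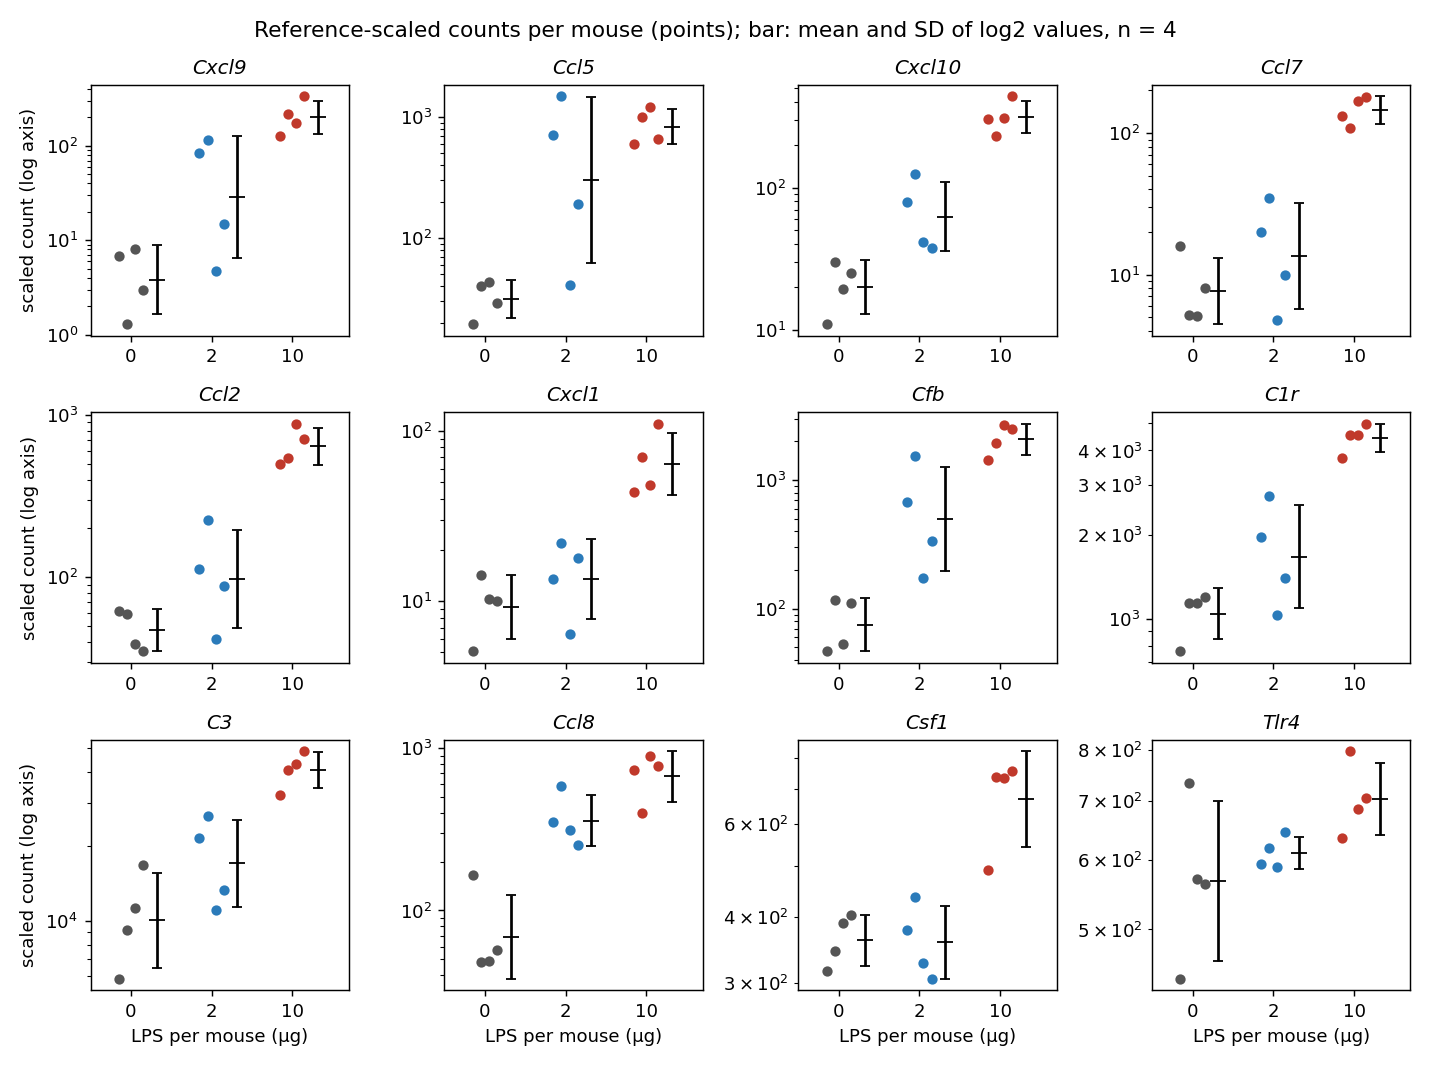
Reference-scaled counts of 12 genes in single mice (points, log axis) against the dose of LPS in µg, with the mean and SD of the log2 values as a bar beside each group of 4 mice. Ccl2 averaged 48.9 in controls and 660.5 at the high dose, and Tlr4 576.7 and 705.2.

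Between the doses 11 genes were higher at the high dose and 0 lower by edgeR, by 1.88-fold to 8.44-fold. The chemokines Ccl7 (3.08 ± 0.52), Ccl2 (2.50 ± 0.44), Cxcl1 (2.19 ± 0.41) and Cxcl10 (2.18 ± 0.41, log2, SE) led. The others included C1r (1.32 ± 0.26), C1s (1.29 ± 0.34), Il23r (1.22 ± 0.29), Il8rb (1.09 ± 0.28), Cd40 (0.98 ± 0.26) and Csf1. The calls of C1s, Il8rb and Cd40 were lost by TMM and by positive controls, and that of Csf1 by positive controls. Of the 12 fits with 1 mouse left out, the calls of C1s and Il8rb were lost in 9 each, that of Cd40 in 10 and that of Il23r in 7. The Il23r call was also lost with limma-voom, with background subtraction and without control mice 2 and 4. Csf1 was at 363.1 ± 39.9 in controls, 361.7 ± 58.6 at the low dose and 680.0 ± 127.1 at the high dose (SD, n = 4). Ccl5, which rose at both doses, differed between them by 0.52 ± 0.76 (adjusted p = 0.746), and Cfb by 1.65 ± 0.57 (0.103). Il1b (0.79 ± 0.33), Nos2 (0.59 ± 0.31), Tnf (1.39 ± 0.66), Il6 (0.56 ± 0.94) and Tlr4 (0.21 ± 0.14) did not pass.

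At an unadjusted p below 0.05, 36 genes were higher and 1 lower at the high than at the low dose. Total count scaling gave 9 higher and 36 lower between the doses, and DESeq2 14 and 4. The count of 11 fell to 7 without control mouse 2 or high-dose mouse 2 or 3, and to 6 without low-dose mouse 4 or high-dose mouse 4. The lists of interferon-stimulated genes (2 of 3 higher; fry adjusted p = 0.00448), chemokine ligands (4 of 18; 0.00448), lymphocyte cytokines (0 of 4; 0.0394) and neutrophil markers (1 of 3; 0.0394) shifted upwards, with 3, 9, 0 and 1 members over the list alone. The shifts of lymphocyte cytokines and neutrophil markers were lost under each of the 5 other scalings, with no filter, with background subtraction, with only the 2 groups fitted, and in 7 and 9 of the 12 fits with 1 mouse left out.

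Tested together against control, the doses changed 32 genes by edgeR, all 32 of them among the 37 of the high dose. The log2 fold changes of both doses correlated at 0.82 across the 165 genes, which are not independent replicates. Both share the control mice, and simulated groups without effect gave a mean correlation of 0.49. With separate controls for each dose, 2 and 2, the measured correlation averaged 0.61 over 6 splits. The covariance was 0.65, and 0.54 on average with separate controls, against a simulated 0.10. The overlap of 4 higher genes stood against 0.897 for independent lists, which leaves out the shared controls. In 100 simulated runs without effect, which called 0 genes, the first 4 and 37 higher genes by p shared 2.74 on average, and 4 in 27 runs. With the controls split in 2 and 2, 0 to 1 gene was called at the low dose, so the overlap could not exceed 1.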

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

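The tests of scale, of low-dose mouse 3 and of H2-Ea were chosen only after the results were seen; the counts over other groupings of the mice were planned.

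In 13 of 126 groups of 4 values, 1 mouse lay far from the other 3, where chance gives about 1 in 20 groups, or 6.3. Control mouse 1 had scaled counts of 2.53 for Il8rb (others 4.99 to 5.18), 165.3 for Ccl8 (others 47.9 to 56.9), 762.6 for C1r, 4.22 for Il23r, 488.4 for C2 and 7.59 for Ccl3. The reference scale of control mouse 1 was 1.19, against 0.917 by positive controls and 0.969 by TMM, which lowers its scaled counts. Its raw counts were 9 for Ccl3 (other controls 7 to 9) and 3 for Il8rb (other controls 4 to 5). Tgfb1 was at 293.6 in control mouse 3. The endogenous total was 98258 in control mouse 2, and the binding density 0.31 in control mouse 4. At the low dose, Il1b was at 46.4 in mouse 2 (others 25.5 to 27.2) and Ltb at 46.2 in mouse 3 (others 94.1 to 106.0). High-dose mouse 1 had 490.0 for Csf1 (others 734.3 to 757.3) and 11.2 for Nos2.

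Other groupings of the mice show how far chance can be excluded. At the high dose 1 of 35 splits of the 8 mice, the real one, gave as many as 37 genes, and the highest other gave 1. Between the doses 1 of 35 gave as many as 11, and the highest other gave 1. Chance is made unlikely for both, though 1 of 35 is the smallest share that these splits can give. For either dose 2 of 100 groupings, the real one included, gave as many as 32 genes. The other one gave more, 38, so chance is made unlikely there but is not excluded. At the low dose 2 of 35 splits gave as many as 4 genes and the highest other gave 9, so chance is not excluded. The split with 9 genes exchanged control mouse 3 and low-dose mouse 3, and the grouping with 38 genes placed low-dose mouse 3 with control mice 1, 2 and 3.

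Genes were lower at the high dose only where the scale came from the whole panel. With the genes called higher by TMM left out of the TMM scale, 4 genes were lower in place of 20. This centres the scale on the other genes, so it would come out alike had they fallen. Counts simulated with only the rising genes changed gave 0 to 7 lower genes by TMM over 20 runs. Their spread was taken from the reference scale, and they gave 23 to 31 higher genes, against 34 by TMM in the data. The simulated number of lower genes may therefore be too low. The median log2 fold change of the genes left unchanged there averaged -0.16, from -0.25 to -0.08 over the runs. The rising genes thus moved the TMM scale in the simulation, but whether they account for 20 lower genes stays open. A fall of the reference genes themselves stays open too: against the positive controls they changed by -0.0301 ± 0.187 (SE), and the -0.29 seen by TMM lies within 2 SE of that. It cannot be told apart with this spread. A change in RNA content of the tissue was not tested.

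In the median of the 37 high-dose genes, low-dose mouse 3 lay at 0.789% of the distance from control to high-dose means, against 55.0%, 68.1% and 39.2% in low-dose mice 1, 2 and 4. A low amount of RNA is argued against, since its reference scale ranked 4 of 4 low-dose lanes, the highest. A mouse without an LPS response under a low-dose label cannot be told apart from a weak response. Genes were called at the high dose without this mouse and 1 control in turn, and compared with the other 3 controls. Above all 3 lay 7 of 38, 19 of 43, 13 of 39 and 8 of 36 genes in the control left out (47 in all), and 10, 14, 9 and 7 (40) in this mouse. In low-dose mice 1, 2 and 4 the sums were 139, 141 and 117. Above all 4 controls lay 7 of the 37 high-dose genes in low-dose mouse 3, where chance gives 7.4. Among these were Ccl8 at 311.6 (highest control 165.3), Cfb at 173.7 (116.5) and Cxcl10 at 41.4 (29.8). So was Il8rb at 33.5 (5.18), the highest of the low-dose mice. Against the sums stands Il8rb: with this mouse fitted alone against the controls by edgeR, and assumed to vary like the other groups, it was the 1 gene of 165 that passed (adjusted p = 0.00196). Each control alone against the other 3 gave 0. A weak response was not tested further.

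H2-Ea and H2-Eb1, class II histocompatibility genes, differed between mice regardless of dose. H2-Ea had scaled counts of 1334 in control mouse 2 and 1074 in low-dose mouse 2, and 5.11 in control mouse 3. The smaller log2 range of both genes, 5.62 with group means removed, exceeded the largest range of 7 leukocyte genes, 2.19, by 3.43. These were C1qa, C1qb, C3ar1, Itgb2, Cd40, Cd4 and Tlr7. More antigen-presenting cells are argued against as the source only as far as these 7 genes follow such cells, which was not tested. Ccr7, not among the 7, had a range of 3.30. Alleles of these genes in the outbred stock may differ, which cannot be told here, with genotypes of 0 mice at hand.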

How the results depend on the processing

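Without the 2 lanes with few fields counted, chosen after seeing the data, 19 genes changed at either dose, 0 at the low dose (23 unadjusted) and 7 between the doses, with 1 list shifted at the low dose. The 37 genes at the high dose numbered 37 there too, 29 of them the same. Of the 37 genes, 22 passed in every one of the 27 alternatives in which they were tested and 15 were lost in 1 or more. Only Ly96 and Tgfb1 fell below 0 in any.

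Total count scaling gave 72 genes at either dose, 92 at the high dose and 45 between the doses, and 7 lists between the doses. DESeq2 size factors gave 59 genes at the high dose, and TMM and DESeq2 size factors each 2 lists between the doses. Positive control scaling gave 7 genes and 2 lists between the doses, and 4 of the reference genes 2 lists. DESeq2 called 58 genes at either dose, 11 at the low dose, 66 at the high dose and 18 between the doses. Limma-voom called 2 genes at the low dose. The series' own test called 21 at the low dose and 28 between the doses unadjusted, and 11, 24 (high dose) and 20 after adjustment. With no filter 2 lists shifted between the doses. With genes above the negative controls in all 12 lanes, which tests fewer genes and 11 of the 17 lists, 0 lists shifted at the low dose and 5 at the high dose. Background subtraction gave 7 genes and 2 lists between the doses. Fits of the groups compared alone gave 1 gene and 1 list at the low dose. The cause of these changes was not tested apart from that of the scaling.

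With 1 mouse left out, the counts ranged from 22 to 36 genes at either dose, 1 to 14 at the low dose, 30 to 45 at the high dose and 6 to 14 between the doses. The lists ranged from 1 to 7 at the low dose, 9 to 12 at the high dose and 2 to 11 between the doses.

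By total count Tlr4 stood at -0.0181 at the low dose, -0.28 at the high dose and -0.26 between the doses, Ly96 at -0.16 and Tgfb1 at -0.11 at the high dose. Tnf at the low dose stood at -0.0507 by limma-voom and -0.13 by the series' own test. With 1 mouse left out, Il6 ranged from -1.34 to 1.29 at the low dose, from -0.00874 to 1.86 at the high dose and from -0.20 to 2.09 between the doses, and Tlr4 at the low dose from -0.0254 to 0.222. None of these genes but Ly96 and Tgfb1 had passed. The cause was not tested.

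The titles number the mice 1 to 4 in each group, but the mice differ. Same-numbered mice correlated at -0.13 to 0.58 (median 0.20, other pairs -0.10), and 7 of 12 correlated best with their own number, a hint of pairing from the data. All 4 pairs of control and high dose lay over 0.1, but only 9 of all 12 pairs, so the numbers were not taken as pairing. With the replicate block the counts were 28 at either dose, 3 at the low dose, 34 at the high dose and 11 between the doses, with 1 list at the low dose and Il6 at the low dose at -0.0326. Not called there were Ccl5 and the chemokine receptors at the low dose, Ccr7, Cxcl2, Nox1, Tgfb1 and the lymphocyte cytokines at the high dose, and C1s, Cd40 and the lymphocyte cytokines between the doses. Depth limits genes near the negative controls: 14 genes were not tested.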

Other observations

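Some genes varied widely between mice of a group, and were chosen after their values were seen. Cfd, complement factor D and a product of fat cells, ranged from 2.50 in high-dose mouse 1 to 2039 in control mouse 4, a log2 range of 9.20 with group means removed, against a median of 0.989 over the tested genes. Masp2, a lectin pathway protease, was at 2.39 in low-dose mouse 3 and at 34.9 or more in the other mice. Il6 and Myd88, the adaptor of Toll-like receptors, were both highest in control mouse 2 (33.7 and 873.6), low-dose mouse 4 (41.6 and 910.6) and high-dose mouse 4 (45.2 and 817.6). Ccl24, an eosinophil chemokine, was at 65.3 in low-dose mouse 3 and at 8.15 to 13.1 in the other low-dose mice. Both Cfd (-3.74 ± 1.79) and Ccl24 (-1.71 ± 0.83, log2, SE) had lower means at the high dose than in controls, which passed with DESeq2 but not with edgeR on the reference scale (adjusted p = 0.174 and 0.176). Ccl24 also passed with edgeR by total count.

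Nox1, an NADPH oxidase, was the one gene of the 37 outside all lists, at 5.05 ± 3.50 in controls and 19.1 ± 16.0 at the high dose (SD, n = 4). It passed with an adjusted p of 0.0494 by edgeR and lost its call in 21 alternatives.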
